A study of Homo sapiens with 2 samples.

How the data were processed

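Total RNA was sequenced from MDA-MB-231 cells, an established human line from a breast cancer, after lentiviral delivery of a control hairpin (shCon) or a hairpin against MPP7 (shMPP7). Per the labels, both cultures were infected at a multiplicity of infection of 10, received fresh medium after 12 h, were inspected by fluorescence microscopy at 72 h and were selected with puromycin for 7 days. There was 1 library per group, and groups were taken from the genotype label of each sample.

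The deposited table listed 58233 Ensembl gene IDs with gene names and gave 4 values per gene. Per the file headers these were a count and an FPKM value (fragments scaled by transcript length and library size) for each library. The deposited counts were estimated counts: 71.8% of the shCon values above 0 and 73.0% of the shMPP7 values above 0 were whole numbers, and the rest were fractions, as when a read is shared between genes. The submitters' processing notes name TopHat2 2.0.9, Cuffdiff and the hg19 build without a role or order, and the tool that made the gene counts is not given in the sources used here. Of the gene IDs, 57895 (99.4%) occurred in GENCODE release 29, an annotation of GRCh38, so the build behind the table stayed unsettled. The table held no coordinates. Positions, gene types, transcript lengths and GC contents were taken from GENCODE 29 on GRCh38 through the Ensembl ID. The length and GC content of a gene were those of its longest transcript.

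The FPKM values as deposited were the main measure. For each gene the log2 ratio was log2((shMPP7 + 1)/(shCon + 1)), which understates the ratio of low genes. Where a name occurred in several lines of the table (215 names), the line with the largest mean was used. Genes with a mean FPKM of at least 1 over both libraries were compared, and a gene was counted as higher or lower by a fixed rule of size, at least 2-fold. With 1 library per group there was no spread between replicates, so no p-value was computed and no comparison below has a replicate check. The table held no fold change, p or q of the authors' own.

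Estimated counts were divided by the library total to give CPM, counts scaled to a fixed library size. The ratio of the 2 CPM values was given with an exact 95% interval (Clopper-Pearson, conditional on the summed count), for which the estimated counts were rounded to whole numbers. Single counts were given with exact Poisson intervals. Outside the gene lists and the alternatives, log2 CPM ratios had 0.1 CPM added to both values. All intervals cover counting error only, not the spread between cultures, and reads counted without molecular identifiers are not independent molecules. Of 12933 genes with a mean FPKM of at least 1, 20.7% had an interval below 1 and 13.3% above it. More counts make it easier for an interval to leave out 1, so this does not by itself mark a changed gene. Apart from the list of MPP7 partners, tallies of such intervals have no share matched on counts beside them. The floor for a gene listed at 0 was set at 3 counts, equal to 0.125 CPM in shCon and 0.122 CPM in shMPP7.

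There were 30 gene lists, fixed before the data were examined. For each, the median log2 ratio of the members with a mean FPKM of at least 1 was placed among the medians of 10000 random lists of the same size, matched on mean expression in 50 bins. The members of the list stayed among the genes that could be drawn. The percentile describes these 2 libraries and is not a test of the conditions. A list was called outside its random lists below percentile 2.5 or above 97.5. By chance 1.5 of 30 lists would lie outside if their genes were drawn independently. An additional list of ATF4 target genes was written after the lists had been seen, before its own values were computed.

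Genes were named by a rule fixed before the data were examined: MPP7, DLG1, LIN7A, LIN7C, EGFR, AKT1, YAP1, CDH1 and VIM, the 10 largest log2 ratios in each direction among genes with a mean FPKM of at least 5, and in each list the 4 members with the largest absolute log2 ratio. Not every list member picked by this rule is given below. Small RNA genes and genes without a symbol were left out of the 10 largest, and clone-based names were read as no symbol, a reading chosen after the data were seen. Further list members, and the genes at least 2-fold apart in CPM with at least 100 counts over both libraries, were chosen after their values were seen. The values of 1 list member are not reported here.

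Near-identical transcripts of the genes at least 2-fold apart in CPM were searched in the GENCODE 29 transcripts with blastn 2.17.0 (at least 97% identity over at least 100 bases, same strand). A trend of the ratio with transcript length and GC content was fitted over protein-coding genes with at least 100 counts and subtracted in an alternative. Other alternatives changed the pseudocount, the minimum, the scaling, the size rule, the treatment of shared names, the gene classes kept, the random lists and the list summary, and replaced FPKM by CPM. The CPM, protein-coding and trend alternatives were chosen after the data were seen.

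The steps were tested on simulated data drawn from the shCon and shMPP7 means of 12897 genes. All 200 genes set 4-fold apart and all 100 genes set 3-fold apart were recovered (100%), and 59 of 12597 genes without a set difference passed the size rule. Of 200 random lists of 25 genes, 6.5% lay outside, and all 100 lists shifted by 0.15 on the log2 scale were recovered. The simulated counts carried counting error only, with the same count-to-FPKM conversion in both libraries and no trend with length or GC content. The deposited values spread more widely than that, so these rates do not apply to them. The genes set apart had a mean FPKM of at least 5, so their recovery by a 2-fold rule was largely fixed in advance. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.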

Results

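MDA-MB-231 is a breast cancer line with mesenchymal features and little E-cadherin. MPP7 (membrane palmitoylated protein 7) is a scaffold of the MAGUK family that binds DLG1 and LIN7 proteins at cell junctions. RNA sequencing was used to ask which transcripts differ when MPP7 is depleted in these cells. The shCon library held 23928620 estimated counts and the shMPP7 library 24513089, with 20451 and 20142 genes above 0. The 20 most abundant genes took 10.0% and 10.4% of the counts, mitochondrially encoded genes 4.50% and 4.67%, and ribosomal protein genes 5.68% and 6.06%. With 1 library per group, every difference below compares these 2 libraries, has no replicate check and carries an interval for counting error only. Single-gene ratios with intervals were not corrected for the trend with transcript length and GC content. Over 10 groups of protein-coding genes, the median log2 CPM ratio was -0.14 in the group with the longest transcripts. It was -0.18 in the group with the lowest GC content, so single ratios of that size need not be particular to a gene.

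MPP7 was expressed at a low level and was lower in the shMPP7 library. The gene (ENSG00000150054, protein coding) lies on chromosome 10, positions 28050993 to 28334486 of GRCh38, on the minus strand. It had 42 counts in shCon (95% interval 30.3 to 56.8) and 21 in shMPP7 (13.0 to 32.1). These were 1.76 and 0.857 CPM, and the CPM ratio was 0.488 (0.275 to 0.843). In FPKM the values were 0.5 and 0.316, a log2 ratio of -0.19, and both lay under the minimum mean of 1 used for other genes. Among 580 protein-coding genes with 42 to 84 counts over both libraries, 20 (3.45%) had a CPM ratio as low as that of MPP7, and 5.69% had a ratio as far from 1 in either direction. MPP7 itself is counted among the 580 and in both shares. With 0.1 CPM added to both values, the log2 CPM ratio was -0.96, and -0.80 once a trend with transcript length and GC content was removed.

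Of 12 measured MAGUK scaffolds and partners of MPP7, 4 had a count interval below 1 and none above it. Of 9861 genes in the same range of counts, 22.0% had an interval below 1 and 11.3% above it, and of all genes with a mean FPKM of at least 1, 20.7% and 13.3%. DLG1, the polarity scaffold that MPP7 binds, had a CPM ratio of 0.903 (0.852 to 0.957), with FPKM of 39.6 in shCon and 32.3 in shMPP7. LIN7C had a CPM ratio of 0.95 (0.849 to 1.06). LIN7A had 1 count in shCon and was listed at 0 in shMPP7, so no fold is given. MPP6, a paralogous scaffold, had 371 and 290 counts, a ratio of 0.763 (0.652 to 0.892). CASK at 0.886 (0.833 to 0.942) and DLG5 at 0.921 (0.877 to 0.967), named after their values were seen, were the other 2. DLG4 and MPP1 had ratios of 0.991 (0.870 to 1.13) and 1.05 (0.975 to 1.13). The median of the list was -0.03, at percentile 19.9 of its matched random lists, and at 4.74 in FPKM and 31.8 in CPM once the trend was removed. The 14 measured genes of the apical-basal polarity complexes had a median of 0.09 (percentile 84.3), of which 2 had a count interval below 1 and none above it. These were the kinase gene PRKCI at 0.832 (0.770 to 0.897) and PARD6B at 0.872 (0.768 to 0.989), named after their values were seen. The intervals of PARD6G, LLGL2, PATJ and PARD6A included 1.

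Most transcripts were close to equal in the 2 libraries. Across 12933 genes with a mean FPKM of at least 1, Spearman's rho between the libraries was 0.980 (a correlation across genes, which are not independent replicates). The size rule counted 115 genes at least 2-fold higher and 114 at least 2-fold lower in shMPP7, together 1.77% of the genes compared. In CPM, among 12154 genes with at least 100 counts, 17 were higher and 12 lower. Among 5022 protein-coding genes with at least 2000 counts, 99.96% lay within 1.5-fold, and the robust SD of the log2 CPM ratio was 0.11 where counting alone gives 0.04.

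Among the 30 gene lists, 5 lay outside the central 95% of their matched random lists, where independently drawn genes would give 1.5. Members of a list can vary together between any 2 cultures, so 5 against 1.5 does not measure an effect of the hairpin. The integrated stress and unfolded protein response, inflammatory cytokine and nuclear-encoded respiratory chain lists lay above, as did a list of fibroblast and endothelial markers with 3 measured genes. The interferon-stimulated genes lay below. The stress, inflammatory, interferon and respiratory chain lists also lay outside in CPM. In CPM 8 lists lay outside, adding the ribosomal protein, immediate early and p53 target lists above and the hypoxia and glycolysis list below. No member of the stress, inflammatory and interferon lists passed the 2-fold size rule in FPKM.

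**Figure D1:**
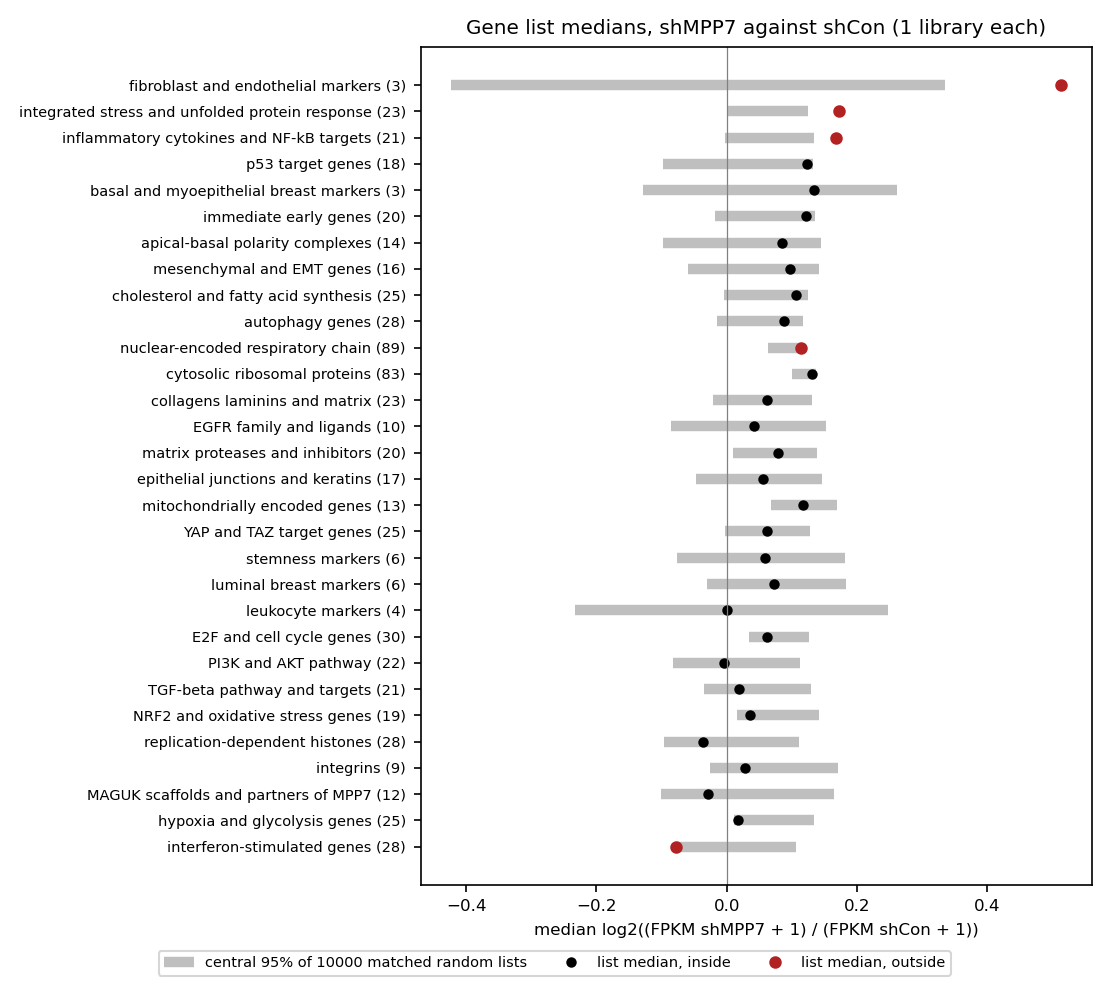
Median log2((FPKM shMPP7 + 1)/(FPKM shCon + 1)) of each gene list (points, red where outside) over the central 95% of 10000 random lists of the same size matched on mean expression (grey bars). The number of measured members is in parentheses, and the integrated stress and inflammatory lists, with medians of 0.17 each, lie to the right of their bars.

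Genes of the integrated stress and unfolded protein response list were higher in the shMPP7 library as a group. The 23 measured members had a median log2 ratio of 0.17 (percentile 99.95 of matched random lists, CPM percentile 100), 20 of them above 0. In counts, 13 members had an interval above a ratio of 1 and 4 an interval below it. CHAC1, a glutathione-degrading enzyme induced by ATF4, had 77 counts in shCon and 191 in shMPP7, a CPM ratio of 2.42 (1.85 to 3.20). ASNS, asparagine synthetase, had 628 and 1144 counts, a ratio of 1.78 (1.61 to 1.96). The pseudokinase gene TRIB3 had a ratio of 1.40 (1.27 to 1.53), and the transcription factor gene ATF4 itself 1.27 (1.22 to 1.32). PSAT1 of serine synthesis stood at 1.26 (1.19 to 1.34), and XBP1, a regulator of the unfolded protein response, at 1.22 (1.15 to 1.31). ATF3 had 76 and 125 counts, a ratio of 1.61 (1.20 to 2.16), but a log2 ratio of 0.04 in FPKM. Of other members, named after their values were seen, HSPA5 had a ratio of 1.05 (1.04 to 1.07), CALR 0.987 (0.974 to 1.00), HSP90B1 0.898 (0.881 to 0.917) and SEL1L 0.883 (0.833 to 0.935).

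Inflammatory cytokine and NF-kB target genes were also higher as a group. The 21 measured members had a median of 0.17 (percentile 99.7, CPM percentile 100), with 17 above 0. In counts, 11 had an interval above 1 and 1 an interval below it. IL1A had 78 and 119 counts, a CPM ratio of 1.49 (1.11 to 2.01), and IL1B 555 and 779 counts, a ratio of 1.37 (1.23 to 1.53). The neutrophil attractant CXCL1 stood at 1.29 (1.22 to 1.36) and the granulocyte growth factor CSF3 at 1.27 (1.23 to 1.30). The NF-kB subunit gene RELB had a ratio of 1.21 (1.12 to 1.29). IL6 and NFKB1 were at 1.01 (0.906 to 1.13) and 1.02 (0.952 to 1.08), and BIRC3, an apoptosis inhibitor induced by NF-kB, was lower at 0.818 (0.755 to 0.885). The list lay inside its random lists without a minimum (percentile 96.7) or with the mean in place of the median (95.07).

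Interferon-stimulated genes were lower as a group. Of 28 measured members 23 had a log2 ratio below 0, with a median of -0.08 (percentile 2.41, CPM percentile 1.15). In counts, 10 had an interval below 1, and 1 (IRF9, at 1.20, 1.01 to 1.41) an interval above it. SAMD9, an antiviral restriction factor, had 276 and 156 counts, a CPM ratio of 0.552 (0.450 to 0.674). Its paralog SAMD9L stood at 0.719 (0.558 to 0.924) and the helicase gene DDX60 at 0.712 (0.586 to 0.864). The ratio of IFIT1 was 0.788 (0.690 to 0.901) and that of IFIT2 0.75 (0.635 to 0.884). The intervals of ISG15, OAS3, MX1 and MX2 included 1. The list was at the edge of its random lists and lay inside them with a pseudocount of 0.1 (percentile 2.96), a minimum mean of 5 (3.17), protein-coding genes only (2.51) or the mean in place of the median (5.89).

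**Figure D2:**
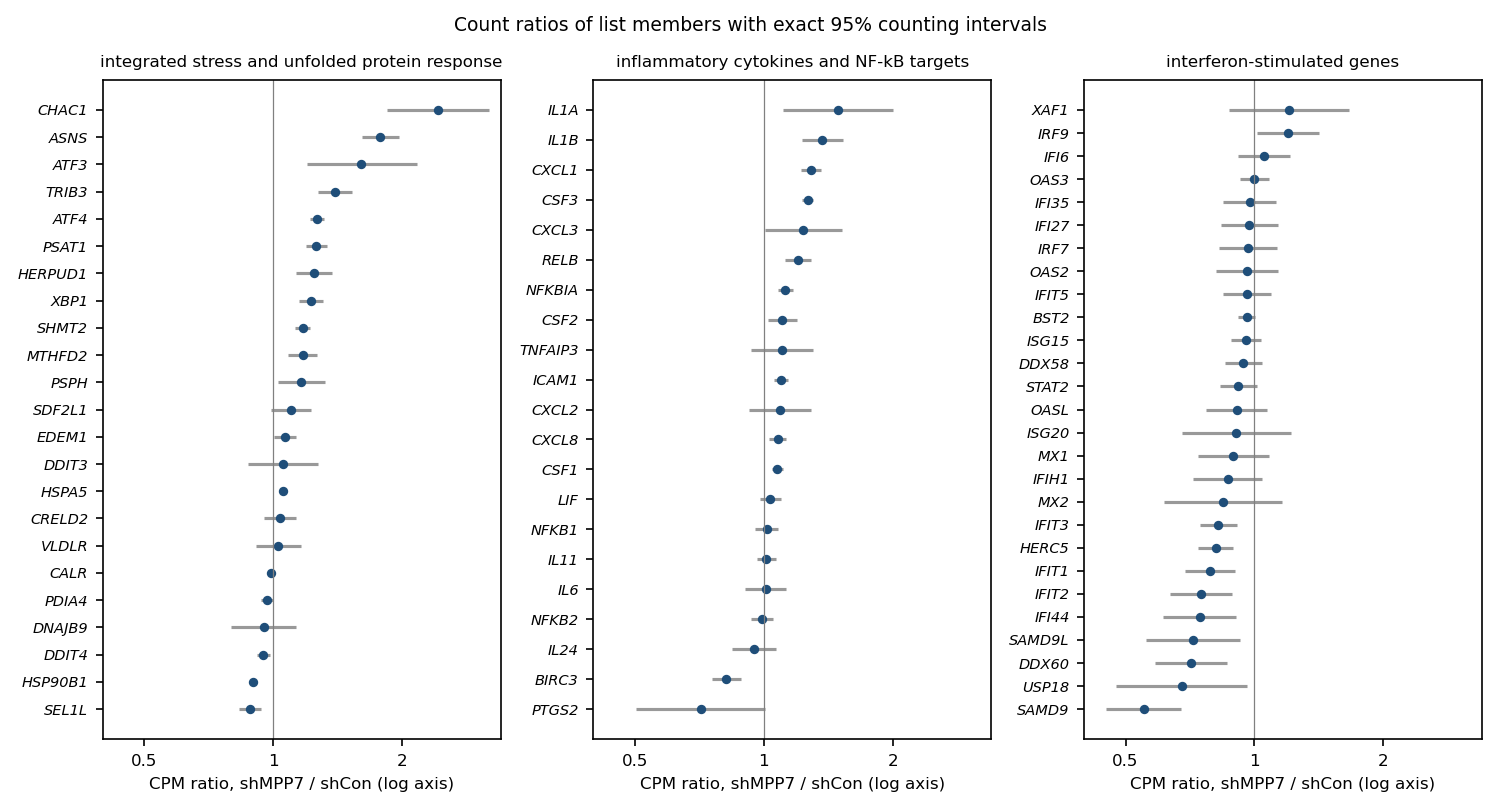
CPM ratio (shMPP7 over shCon, log axis) of the measured members of 3 gene lists (1 interferon-stimulated gene is not drawn), with exact 95% counting intervals as bars and a line at a ratio of 1. CHAC1 (2.42) and ASNS (1.78) stand highest in the stress list, and SAMD9 (0.552) is the lowest of the interferon-stimulated genes.

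The respiratory chain and the other abundant housekeeping classes sat slightly above or at their matched random lists. The 89 measured nuclear-encoded respiratory chain genes had a median of 0.11 (percentile 98.1, and 99.99 in CPM, where 87 were measured), of which 77 were above 0, and NDUFC1 had a CPM ratio of 1.19 (1.05 to 1.34). In counts, NDUFAF5 and ATP5S, with log2 ratios of 0.70 and 0.61 in FPKM, had intervals that included 1. The only member past the 2-fold size rule was NDUFC2-KCTD14, with a log2 ratio of -1.68 in FPKM. It was lower, with 32.2 and 1.56 counts and a CPM ratio of 0.061 (0.00708 to 0.239). The list lay inside its random lists with a pseudocount of 5 (percentile 95.6), without a minimum (86.5), with the mean (88.2) or once a trend with length and GC content was removed (89.97). The 83 cytosolic ribosomal protein genes had a median of 0.13 (percentile 93.5, CPM percentile 100), and 66 had an interval above 1. At high counts the interval is narrow, so a small ratio suffices for that, and no share matched on counts was computed. RPL37 stood at 1.15 (1.11 to 1.18) and RPL13A at 1.13 (1.12 to 1.14). The 13 mitochondrially encoded genes had a median of 0.12 (percentile 43.8), with MT-CO3 at 1.10 (1.09 to 1.11). Members of these abundant classes could themselves be drawn into the matched random lists, which pulls those lists toward the class. Against unmatched random lists the ribosomal list stood at percentile 99.99 in FPKM, the respiratory chain list at 99.95 and the mitochondrial list at 91.1. The ribosomal list stood at percentile 96.6 in FPKM and 100 in CPM once the trend with length and GC content was removed. Over 11366 protein-coding genes with at least 100 counts the median log2 CPM ratio was 0.05 in the 20% of genes with the shortest transcripts and -0.12 in the 20% with the longest.

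**Figure D3:**
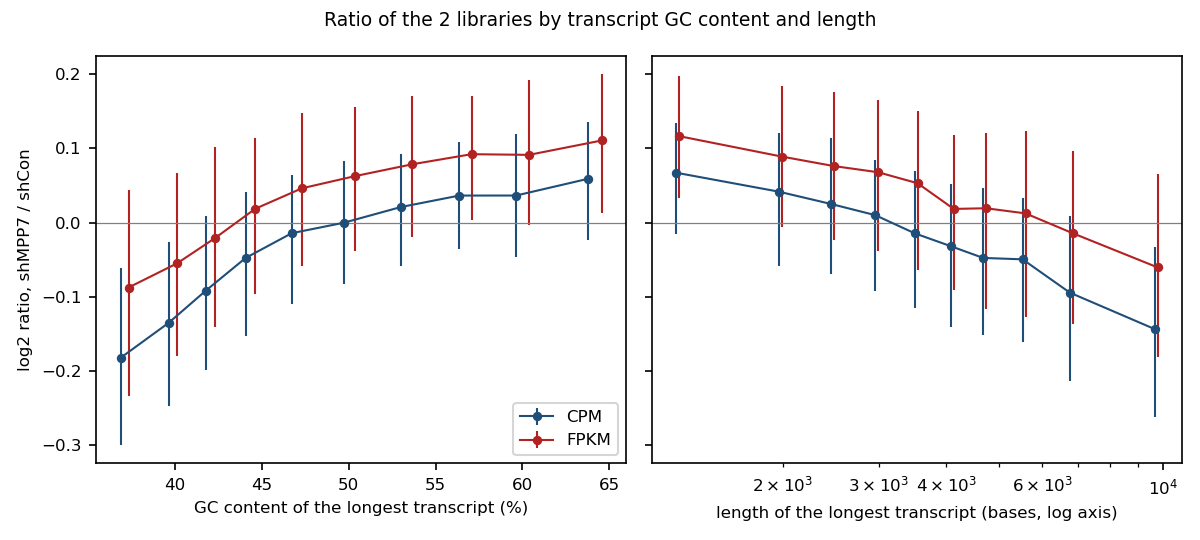
Log2 ratio of shMPP7 to shCon in CPM (blue) and FPKM (red, drawn slightly to the right) against GC content (left) and length (right, log axis) of the longest transcript, over 11366 protein-coding genes with at least 100 counts in 10 groups of similar size. Points are medians and bars span the quartiles, and the CPM median is higher at higher GC content and lower at greater length.

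The mesenchymal, epithelial, luminal, basal and stemness lists lay inside their random lists in FPKM and in CPM. VIM, the mesenchymal intermediate filament, had a CPM ratio of 1.12 (1.11 to 1.13), and CDH1 (E-cadherin) had 3 counts in shCon and 1 in shMPP7, both at or under the floor of 3 counts, so no fold is given. The 16 mesenchymal genes had a median of 0.10 (percentile 83.5), and in CPM, where 15 were measured, of -0.07 (11.9). Within them CDH11, a mesenchymal cadherin, was lower, with 120 and 53 counts and a ratio of 0.431 (0.306 to 0.6), and ZEB1 stood at 0.836 (0.752 to 0.929). The transcription factor gene FOXC1 was higher at 1.32 (1.14 to 1.52). The 17 epithelial junction and keratin genes had a median of 0.06 (percentile 49.7). Once the trend with length and GC content was removed this list stood at percentile 4.69 in FPKM and, outside its random lists, at 2.31 in CPM, where 19 genes were measured. Its members included the desmosomal gene DSP at 0.835 (0.775 to 0.898) and KRT7 at 1.09 (1.06 to 1.12). Luminal markers (6 measured, median 0.07, percentile 42.8), basal and myoepithelial markers (3, 0.13, percentile 82.1) and stemness markers (6, 0.06, percentile 45.5) lay inside their random lists. Among luminal genes GATA3 stood at 1.18 (1.02 to 1.36), among basal genes S100A2 at 0.829 (0.75 to 0.915), and among stemness genes BMI1 at 0.938 (0.871 to 1.01).

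The lists of growth factor signalling genes lay inside their random lists in FPKM. EGFR had 5067 and 4523 counts, a CPM ratio of 0.871 (0.837 to 0.907), and AKT1 a ratio of 1.04 (1.01 to 1.08). The median of the 10 EGFR family and ligand genes was 0.04 (percentile 51.2). Of these ligands EREG was at 0.752 (0.690 to 0.820) and HBEGF at 1.14 (1.08 to 1.20). The 22 PI3K and AKT pathway genes had a median of 0.00 (percentile 30.7), with the catalytic subunit gene PIK3CA at 0.757 (0.664 to 0.863), the phosphatase gene INPP4B at 0.738 (0.660 to 0.825) and the kinase gene SGK1 at 1.16 (1.03 to 1.31). YAP1 stood at 0.942 (0.901 to 0.985). The 25 YAP and TAZ target genes had a median of 0.06 (percentile 46.5), among them CTGF at 1.19 (1.14 to 1.24) and FJX1 at 1.23 (1.14 to 1.32). TGF-beta pathway genes (21, median 0.02, percentile 22.2) included SMAD7 at 1.20 (1.07 to 1.35). Immediate early genes (20, median 0.12) lay at percentile 95 in FPKM and at 99.9 in CPM (58.2 and 94.4 with the trend removed), with EGR1 at 1.30 (0.998 to 1.69) and FOS at 0.824 (0.521 to 1.30).

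The lists of matrix, protease and integrin genes lay inside their random lists. The 23 collagen, laminin and matrix genes had a median of 0.06 (percentile 54.4), the 20 matrix proteases and inhibitors 0.08 (percentile 52.2) and the 9 integrins 0.03 (percentile 15.4). In CPM the medians were -0.03 (percentile 7.52), -0.04 (6.82, with 25 measured) and -0.01 (30.3, with 10 measured). With the trend removed the collagen list stood at percentile 87.3 in FPKM and 2.95 in CPM. COL1A1 stood at a CPM ratio of 1.19 (1.01 to 1.41), COL6A3 at 1.13 (1.06 to 1.21), and PLAT, tissue plasminogen activator, at 1.19 (1.13 to 1.25). The collagen receptor gene ITGA2 was at 0.862 (0.814 to 0.911), ITGAV at 0.827 (0.787 to 0.868) and the sheddase gene ADAM10 at 0.844 (0.801 to 0.890). The 3 measured fibroblast and endothelial markers (PECAM1, COL1A1 and PDGFRB) had a median of 0.51 in FPKM (percentile 99.5) and stood at percentile 50.7 in CPM, where 4 were measured. PECAM1 had 68 and 73 counts, a ratio of 1.05 (0.743 to 1.48). The 4 measured leukocyte markers had a median of 0.00 (percentile 46.5), with CD14 at 1.42 (1.12 to 1.80).

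Proliferation and metabolic lists lay inside their random lists in FPKM as deposited, and the p53 and hypoxia lists lay outside in other settings. The 30 E2F and cell cycle genes had a median of 0.06 (percentile 20.2). TOP2A, the proliferation-associated topoisomerase, had 12449 and 10034 counts, a CPM ratio of 0.787 (0.766 to 0.808), while CDT1 stood at 1.18 (1.08 to 1.28). The 18 p53 target genes had a median of 0.12 (percentile 96.5, CPM percentile 97.9). Of these, PLK3 stood at 1.30 (1.10 to 1.54), SESN2 at 1.28 (1.11 to 1.48) and CDKN1A at 1.11 (1.05 to 1.17), while MDM2 was at 0.880 (0.802 to 0.967). With the trend removed the p53 list stood at percentile 98.0 in FPKM and 82.8 in CPM. The 25 hypoxia and glycolysis genes had a median of 0.02 (percentile 3.71, CPM percentile 2.42), and in counts 14 had an interval below 1 and 1 (ALDOC, at 1.23, 1.02 to 1.49) above it. VEGFA stood at 0.891 (0.866 to 0.918) and NDRG1 at 0.889 (0.862 to 0.917). With the trend removed the hypoxia list stood at percentile 0.18 in FPKM and 0.04 in CPM. Cholesterol and fatty acid synthesis genes (25, median 0.11, percentile 92.8) included ELOVL6 at 0.842 (0.786 to 0.902). NRF2 and oxidative stress genes (19, median 0.04, percentile 7.58) included AKR1C1 at 0.647 (0.561 to 0.746), a gene with close paralogs. Autophagy genes (28, median 0.09, percentile 85.0) included RB1CC1 at 0.699 (0.623 to 0.784). MAP1LC3A, TFEB and ATG10 of that list, with log2 ratios of 0.72, 0.61 and 0.60 in FPKM, had count intervals that included 1.

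The 10 largest FPKM ratios in the higher direction were PSMC1P5, LUZP6, HIST2H2AA3, SNRPCP11, GRIK4, DLGAP1-AS1, RGPD5, SMIM11B, GOLGA6L4 and LINC00680. The 10 largest in the lower direction were SNRPCP13, HMSD, BLOC1S5-TXNDC5, KLRC4-KLRK1, PCDH11X, DENND2A, NAMPTP3, PIGY, FHIT and SMIM11A. Of these 20 genes, 8 had under 20 counts over both libraries, the same number were listed at 0 in 1 library, and 5 with at least 100 counts were also 2-fold apart in CPM. PSMC1P5 had an FPKM of 97.5 in shMPP7 and was listed at 0 in shCon, on 3.69 estimated counts. For GRIK4, a glutamate receptor subunit gene, FPKM was 2.73 and 39.7 while the counts were 264 and 246, a CPM ratio of 0.910 (0.761 to 1.09). FHIT had 50.1 and 4.50 FPKM on 80 and 83 counts. HMSD had 80.05 and 1.92 FPKM on 91.4 and 83 counts. DENND2A was lower on both scales, with a CPM ratio of 0.649 (0.556 to 0.757).

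Of all 229 genes past the size rule in FPKM, 134 (58.5%) had under 20 counts over both libraries, against 2.28% of all genes compared. A further 53 had 20 to under 100 counts, and 42 had at least 100. Of the 42 genes, 13 (31.0%) were also at least 2-fold apart in CPM in the same direction and 12 had the opposite sign in CPM. Protein-coding genes made up 64 of the 229, and clone-based names 102.

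**Figure D4:**
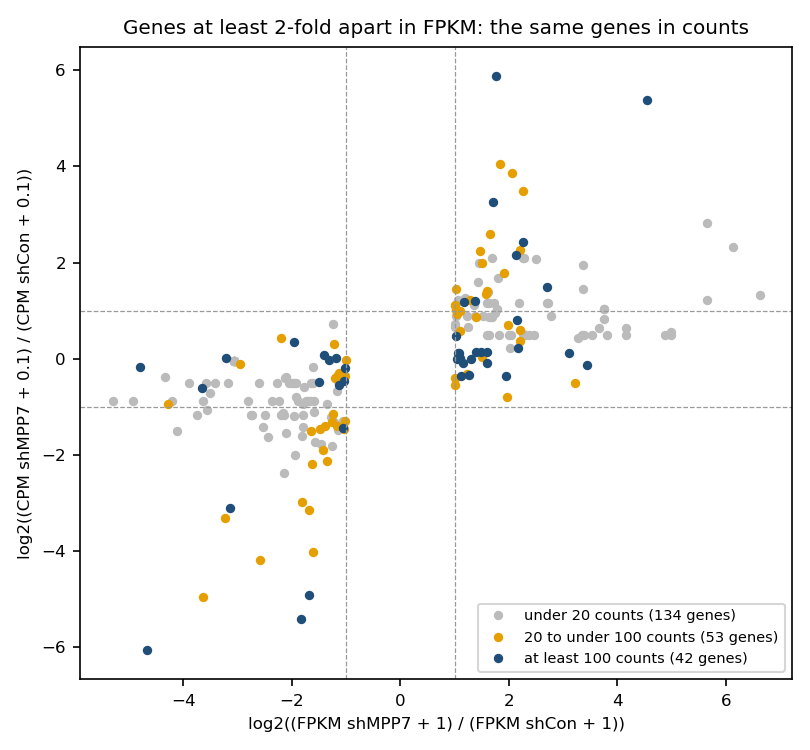
Log2 ratio in FPKM (horizontal, pseudocount 1) against log2 ratio in CPM (vertical, pseudocount 0.1) for the 229 genes at least 2-fold apart in FPKM, coloured by the estimated counts over both libraries, with dashed lines at 2-fold. Many of the 42 genes with at least 100 counts lie near 0 on the vertical axis, and 13 lie beyond 2-fold in the same direction.

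Among the replication-dependent histone genes (28 measured, median -0.04, percentile 18.6), 4 were at least 2-fold higher and 1 at least 2-fold lower in FPKM. HIST2H2AA3 had 1.52 counts in shCon and 164.9 in shMPP7, a CPM ratio of 80.5 (21.9 to 671) from counts rounded to 2 and 165, while its near-identical copy HIST2H2AA4 had 481.4 and 275.1. Together both genes had 482.9 and 440 counts. The counts of each are fractional, and the interval does not cover how reads were divided between the copies. HIST1H4J had 20.5 and 6 counts, a ratio of 0.293 (0.0962 to 0.756), and HIST1H2BO 2 and 12 counts, a ratio of 5.86 (1.30 to 53.9). With the trend removed the list stood at percentile 0.15 in FPKM and 12.6 in CPM, where 14 were measured, and with the mean in place of the median at 96.93 in FPKM without that removal. Histone transcripts carry no poly(A) tail, and their read yield depends on how a library was made.

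Of the 29 genes at least 2-fold apart in CPM with at least 100 counts, chosen after their values were seen, 8 had no near-identical partner in the transcript search. The protein-coding ones among these 8 were CHAC1, TERT, CDH11 and ZNF821. TERT, the catalytic subunit of telomerase, had 29 counts in shCon and 71 in shMPP7, a CPM ratio of 2.39 (1.53 to 3.82). The zinc finger gene ZNF821 had 42.6 and 91.6 counts, a ratio of 2.09 (1.44 to 3.07), and CHAC1 and CDH11 are given above. HSPA6, a heat-inducible chaperone of the HSP70 family, had 255 and 115 counts, a ratio of 0.440 (0.350 to 0.551), and its near-identical pseudogene HSPA7 had 4.99 and 5.97.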

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

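The CPM, protein-coding and trend alternatives were chosen after the data were seen. No paired analysis was possible because there was 1 library per group and no test, and for the same reason no library could be left out. Depth limits low genes such as MPP7, with 42 and 21 counts, and LIN7A and CDH1, with 3 counts or fewer per library. The MPP7 log2 ratio was negative under every alternative run, from -0.05 (pseudocount 5) to -0.96 (CPM, at least 100 counts setting). Scaling both libraries to the same FPKM sum moved the median log2 ratio of all genes from 0.04 to -0.06.

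Against 115 higher and 114 lower genes, there were 202 and 210 with a pseudocount of 0.1, 44 and 42 with a pseudocount of 5, and 175 and 185 without a minimum. A minimum mean of 5 gave 47 and 33, a size rule of 1.5-fold 316 and 306, and 4-fold 47 and 52. Protein-coding genes alone gave 34 and 30. CPM with a pseudocount of 1 gave 13 and 14, CPM with at least 100 counts 17 and 12, and CPM with the trend removed 11 and 17. Pseudocount, minimum, size rule and gene class change the number that can pass by construction, and the CPM settings are weighed among the other observations.

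The list values here are the list median minus the middle of its random lists. The stress list lay outside under all 16 alternatives (percentile 98.0 to 100), the inflammatory list under 14 (95.1 to 100) and the interferon list under 12 (0.01 to 5.89), each with the same sign throughout. The respiratory chain list lay outside under 12. Centring the log ratios on their median subtracts the same value from every gene, so it cannot move a percentile. These tallies therefore do not count independent checks. The stress value of 0.108 became 0.180 with the mean in place of the median and 0.178 in CPM with the trend removed. For cytosolic ribosomal proteins 0.0131 became 0.0326 without a minimum, 0.0894 with unmatched random lists, 0.0652 in CPM, 0.0640 in CPM with at least 100 counts and 0.0390 in CPM with the trend removed. For fibroblast and endothelial markers 0.549 became 0.0302 without a minimum and 0.00229, 0.0103 and 0.0393 in those 3 CPM settings. The mesenchymal value of 0.0448 became -0.0718 in CPM with at least 100 counts, and the mitochondrial value of -0.0029 became 0.0764 with unmatched random lists. For the respiratory chain 0.0262 became 0.0737 with unmatched lists, 0.0663 in CPM and 0.0665 in CPM with at least 100 counts. For histones -0.0461 became 0.157 with the mean and -0.159 with the trend removed. The cause of these moves was not tested.

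Of the named genes other than MPP7, 9 of 1970 values reversed. FHIT (-3.22) was at 0.0141, 0.0178 and 0.0552 in CPM, CPM with at least 100 counts and CPM with the trend removed, and GRIK4 (3.45) at -0.125, -0.135 and -0.126. In CPM with the trend removed LUZP6 was at -0.0683, PCDH11X at 0.0377 and SNRPCP11 at -0.108. A further 296 values moved by more than the counting interval and 1665 did not.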

Other observations

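Tests of the FPKM and count differences and of shared reads were chosen after the results were seen, as was the test of the respiratory chain list alone. The test of the transcript trend over all lists, and that of a second list of ATF4 targets, were written before their outcome was known.

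A further group of genes stood apart when ATF4 targets outside the stress list were examined. ATF4 is the transcription factor of the integrated stress response and controls amino acid transport and tRNA charging. As a hypothesis, a shift of ATF4 target genes in general may underlie the position of the stress list. A second list of 29 targets, sharing no gene with that list, was predicted to lie above the central 95% of its matched random lists in FPKM and in CPM. Its 26 measured genes had a median log2 ratio of 0.28 in FPKM (percentile 100, random lists 0.01 to 0.13) and 0.22 in CPM (percentile 100). After the trend with transcript length and GC content was removed the medians were 0.22 and 0.15, each at percentile 100. In counts 20 members had an interval above 1 and 4 an interval below it.

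Within this second list, the transcription factor gene JDP2 had 138.0 counts in shCon and 225 in shMPP7, a CPM ratio of 1.59 (1.28 to 1.98). The neutral amino acid transporter gene SLC1A4 stood at 1.41 (1.24 to 1.60) and CEBPB at 1.38 (1.30 to 1.46). Of the tRNA ligase genes, MARS had a ratio of 1.29 (1.23 to 1.35), WARS 1.23 (1.17 to 1.28), CARS 1.22 (1.16 to 1.29) and AARS 1.21 (1.15 to 1.28). PCK2 of mitochondrial gluconeogenesis was at 1.29 (1.15 to 1.46). The members with an interval below 1 were EPRS at 0.899 (0.853 to 0.947), SLC38A2 at 0.906 (0.864 to 0.951), ALDH18A1 at 0.95 (0.908 to 0.994) and LARS at 0.952 (0.911 to 0.996). With 1 culture per hairpin, a difference in nutrients, density or selection between the 2 cultures was not separated from the depletion of MPP7.

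The ratio of the libraries followed transcript properties. Over 11366 protein-coding genes with at least 100 counts, Spearman's rho across genes of the log2 CPM ratio was 0.44 with GC content and -0.36 with transcript length (genes are not independent replicates). The median log2 CPM ratio was -0.15 in the 20% of genes with the lowest GC content (median 38.4%) and 0.05 in the 20% with the highest (61.4%). The shortest and longest 20% of transcripts, at 0.05 and -0.12, had median lengths of 1675 and 7778 bases. The trend took up 16.8% of the variance of the log2 CPM ratio. As one group chosen after the values were seen, 272 of 392 ZNF-named zinc finger genes had a lower CPM in shMPP7. Their median of -0.13 (percentile 0) became -0.06 after the trend was removed (percentile 0.03), and their median GC content was 43.3% against 48% for all genes in the fit.

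If this trend alone placed the 5 lists outside their random lists, at most 50% of them would stay outside once it is removed. Instead 80% stayed, 4 of the 5. The interferon-stimulated genes were at percentile 0.03 in FPKM and 0.01 in CPM after the removal, the stress list at 99.9 and 100, and the inflammatory list at 98.4 and 99.4. The inflammatory CPM median went from 0.116 to 0.056, so the trend took up part of it. The stress CPM median went from 0.132 to 0.164 and the interferon CPM median from -0.125 to -0.151. For the respiratory chain list the trend stays open, since it stood at percentile 89.97 in FPKM and 98.2 in CPM after the removal. In all, 7 lists lay outside in FPKM after the removal, now with the p53 list (98.0), the hypoxia list (0.18) and the histones (0.15, but 12.6 in CPM with 14 genes) among them. The fibroblast and endothelial list stayed outside in FPKM (99.5) but rested on 3 genes and stood at percentile 65.0 in CPM, with 4 genes. A biological difference between the hairpins stays open for the stress, inflammatory and interferon lists, as a hypothesis without a replicate.

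For the 229 genes at least 2-fold apart in FPKM, the tables point to the FPKM values more than to the counts. A conversion from counts to FPKM that differs between the libraries would leave most of the well-counted genes under 2-fold in CPM, and 31.0% of them were 2-fold apart in CPM in the same direction. Few counts behind the value is a likely source for many, with 58.5% of the 229 genes under 20 counts. A biological difference in transcript forms would also alter an FPKM value at an equal count, so the 31.0% does not separate it from a technical difference in the conversion, and it stays open.

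For the 29 genes at least 2-fold apart in CPM with at least 100 counts, reads divided differently between near-identical or overlapping genes are a candidate explanation. Of 21 such genes with a near-identical partner, 7 (with both genes of the pair SMIM11A and SMIM11B among them) had partners that differed the opposite way by a similar amount and 1 had partners that differed the same way by as much. That 1 was RGPD6 (458.5 and 13.1 counts), whose partners, RGPD5 and others, together had 2931 and 2598 counts. RGPD5 on its own differed the opposite way (195.8 and 569.4). With all its partners, RGPD6 summed to 3389 and 2611 counts. Among the 7, AC068631.2 rested on a small difference of its abundant partner DNAJB11 (98.1 and 96.0 CPM). Summed with their partners, 2 of the 21 (HSPA6 and FP236383.1) stayed at least 2-fold apart. This count does not by itself point to shared reads, since an abundant partner keeps the sum near equal whatever the gene does. SORD2P, for example, had 34.3 and 73 counts beside 2063 and 2096 of its partner SORD. AC026464.4 had 89.5 and 34.6 counts beside 2594 and 2834 of VPS4A. SMIM11A and SMIM11B together had 298 counts in shCon and 294 in shMPP7, and the BLOC1S5-TXNDC5 family 14328 and 14890. For HSPA6, reads shared with its pseudogene HSPA7 are argued against, since the sum of both was still 2.20-fold apart. Of the 29 genes, 25 (86.2%) had fractional counts, as reads divided between transcripts of several genes give, against 35.1% of all genes with at least 100 counts. CHAC1, TERT, CDH11 and ZNF821 had no partner in the search, so the summing tests nothing for them. The counts of CHAC1, TERT and CDH11 were whole and those of ZNF821 fractional, so shared reads stay open for ZNF821.

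Among the count differences, 2 antisense RNA genes overlapped BCL2L1 on the opposite strand, and whether the counting used strand is not given in the sources used here. ABALON had 10 counts in shCon and 119 in shMPP7, and AL117381.1 had 100.5 in shCon and was listed at 0 in shMPP7. BCL2L1 itself had 9080 and 9723 counts. The noncoding RNA gene FP236383.1, on chromosome 21 of GRCh38 at positions 8380665 to 8410645 and spanning a copy of the RNA5-8S5 ribosomal RNA gene, had 343 and 1574 counts, and its near-identical copy FP671120.1 had 409.5 and 438.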
